A study of Mus musculus with 10 samples.

How the data were processed

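The data were gene-by-cell matrices of 10 droplet libraries of lineage-negative, c-Kit-positive mouse cells, 1 library per group, prepared with a Chromium 3' kit per the labels' protocols. The deposited values were raw UMI counts per gene and called cell barcode, made by the authors with Cell Ranger on build mm10 per the submitters' processing notes. Those notes name version 7.0.1 for all samples. Per the file headers, the version was 7.0.1 for the 2 libraries at 16 h of LPS, 6.1.2 for the 2 libraries of Il10-/- mothers and 5.0.1 for the other 6. Whether intronic reads were counted is not stated in headers or labels. All matrices held the same 32285 genes, with symbols given in the files. Gene positions and intron lengths came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, which held 32158 of these genes.

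Groups followed the sample titles. All 4 Il10+/- libraries carry a 3 h LPS treatment label although 2 titles say PBS, and the titles were used. The labels state that both sexes were pooled.

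From the 56512 deposited barcodes, those with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs on mitochondrial genes were retained (53492). Scrublet in scanpy 1.11.5 called 1168 doublets, library by library, 1.34% to 2.77% of each library, and 52324 cells were kept. Kept UMIs per library ran from 114593629 to 184972368. The adult PBS, 3 h and 16 h libraries had 7301, 4638 and 3849 kept cells, with medians of 17520.0, 22840.0 and 32583 UMIs per cell. The wild-type fetal libraries had 4984, 5319 and 3734 cells, with medians of 29468, 28566 and 37402 UMIs. Libraries of wild-type mothers had 6090.0 and 6203 cells with medians of 29771 and 25786 UMIs at PBS and LPS, and those of Il10-/- mothers 4854 and 5352 cells with medians of 30650 and 30094 UMIs. Median mitochondrial shares ran from 2.49% to 3.22%, except 4.89% in the fetal 16 h library.

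Called doublets entered the clustering and were dropped afterwards. Cells were clustered jointly with Seurat 5.3.0 in R 4.3.3, using reciprocal PCA between libraries, 2000 variable genes, 30 components, 20 neighbours and Louvain resolution 0.8. Genes of the response lists were left out: acute NF-kB, both interferon lists, STAT3, immediate early and glucocorticoid. Cell cycle, haemoglobin, ribosomal, mitochondrial and sex-linked genes were left out too, the aim being classes not defined by the treatment response. Other granule genes, such as Camp, were not excluded, so classes may depend in part on the granule response. Marker sets used for naming also held members of response lists, such as Ly6a, S100a8 and S100a9. Clusters were named from 17 marker sets. Of the 20 clusters, 4 stayed unnamed: clusters 7 and 18 had markers of 2 classes, cluster 13 was 50.5% doublets before their removal and cluster 14 had too few markers. Names end in "-like" because they rest on transcripts alone. Shares carry exact Clopper-Pearson 95% intervals.

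Counts were summed over kept cells per library, and per library and class. For comparisons of 1 library with 1, CPM values carry exact Poisson 95% intervals and ratios of CPM exact binomial ones. The log2 ratio used CPM plus 5. A level of 0 was read against a floor of 3 counts. No test or p was computed for these comparisons. Gene lists were summarised by the median log2 ratio of members at 5 CPM or more in either library, its percentile among 10000 random lists matched on mean expression, and a bootstrap 95% interval over members (2000 draws). The bootstrap treats members as independent and does not cover variation between animals. Counts of genes or list members at 2-fold describe size only and do not call genes changed.

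The only contrast with independent repeats, LPS at 3 h against PBS in 3 fetal litter types, was tested on the summed counts of 6 libraries with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood fit, litter type as an additive block, 2 residual degrees of freedom, Benjamini-Hochberg threshold 0.05). It was repeated within each class holding at least 50 cells in all 6 libraries. The litter types differ in genotype, mother and, for 1 of them, software version, which the block removes. The 28 gene lists were tested with camera (preset correlation 0.01, and estimated) and fry of limma 3.58.1 on voom values, adjusted over lists. List counts adjusted over the list alone used the same edgeR p values.

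Gene lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The gene lists held 537 distinct genes, 534 of them in the files. In the tested contrast the rule named the 10 genes with the largest change in each direction past adjusted p 0.05, with the same sign in all pairs and a mean of at least 20 CPM. In other comparisons it named the 8 genes with the largest log2 ratio in each direction with at least 20 CPM in either library and an interval of the ratio excluding 1, plus up to 4 members per list by the same criteria, plus Il10. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Y-linked and Xist transcripts and gene models named Gm or Rik were left out. A gene that the rule named in the fetal 3 h ratio is not reported here. Genes outside the rule are given values only for comparison with a named value: Rbm3, Socs3 and Isg15 across libraries, and the mast cell genes across libraries. Some list members outside the rule, such as Hspa1a, Hspa1b and Aldoa in the tested contrast, are named without values to explain list counts or overlaps.

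The edgeR step was tested on simulated counts for 14882 genes at the real means and library sizes, with a dispersion of 0.0048 and 200 genes changed. It recovered 177 of them: 40 of 50 at 1.5-fold up, 50 of 50 at 2-fold up, 42 of 50 at 0.667-fold and 45 of 50 at 0.5-fold, and it called 9 unchanged genes. All simulated libraries shared 1 mean profile, without litter differences, and all genes shared that dispersion. The figures therefore do not show how the test performs with the litter differences and unequal dispersions of real data. Alternatives tried were DESeq2 1.42.0, RLE size factors, no count filter, no litter block, each litter type left out, all deposited barcodes, doublets kept, class shares set equal, a pseudocount of 1 CPM, all list members with at least 1 UMI, TMM scaling, single classes, other resolutions and clustering without correction. Chosen after the data were seen were short-intron list members, leaving out the low-UMI cluster and a mitochondrial limit of 5% for the cells kept. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. No reads were realigned, and no free-RNA correction was made.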

Results

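The series holds single-cell RNA counts from haematopoietic progenitors of mice, sorted as lineage-negative, c-Kit-positive cells from the fetal liver at E18.5 or from the bone marrow of adults aged 8 to 12 weeks. There were 10 libraries in 10 groups, so each group had 1 library and no replicate. Wild-type adults and wild-type fetuses each gave libraries after PBS, after 3 h of in vivo lipopolysaccharide (LPS, the bacterial outer-membrane ligand of Toll-like receptor 4) and after 16 h of LPS. Il10+/- fetuses of wild-type mothers and of Il10-/- mothers each gave a PBS and a 3 h LPS library. Groups follow the sample titles, because the treatment label of all 4 Il10+/- libraries reads LPS although 2 of their titles say PBS. Deposited totals ran from 119850941 to 192072931 unique molecular identifiers (UMIs) per library, and 3734 to 7301 cells per library were kept. Median depth per kept cell ran from 17520.0 UMIs in the adult PBS library to 37402 in the fetal 16 h library. Levels (CPM) are UMIs summed over kept cells and scaled to a common library total. Intervals are exact 95% Poisson or Clopper-Pearson intervals and cover counting error only, not variation between animals. Ratios are log2 of CPM with 5 added, so a fold computed from the printed levels can differ from the printed log2 value.

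Il10, the targeted gene (ENSMUSG00000016529, GRCm38 chromosome 1, 131019845 to 131024974), encodes the anti-inflammatory cytokine named in the design. It had 0 UMIs in the adult PBS library, which allows up to 0.0255 CPM, 16 at 3 h of LPS (0.140 CPM, 0.0798 to 0.227) and 32 at 16 h (0.242 CPM, 0.165 to 0.341). Wild-type fetal cells held 0 UMIs at PBS, 2 at 3 h and 9 at 16 h. The Il10+/- libraries stood higher: 168 UMIs (0.908 CPM, 0.776 to 1.06) and 139 (0.861 CPM) at PBS and LPS for wild-type mothers, and 148 (0.968 CPM) and 116 (0.724 CPM) for Il10-/- mothers. Pooled, the 4 Il10+/- libraries held 571 UMIs against 11 in the 3 wild-type fetal libraries. They held 325 against 3 in early erythroid, 54 against 4 in HSC and multipotent and 44 against 0 in megakaryocyte progenitor-like cells. Such counts follow class size in part. Levels in the pooled Il10+/- libraries were 0.972, 0.659 and 1.69 CPM in these 3 classes. They were 1.47 CPM in basophil and mast cell and 0.357 CPM in neutrophil progenitor-like cells. The counts come from 3' tags, and the files do not say whether those lie in the altered part of the allele. They therefore check neither the genotype nor the loss of functional Il10, and the fetal cells cannot report the mothers' genotype.

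The first comparison asks how adult and fetal progenitors of wild-type animals differ 3 h after LPS. In every comparison of adult with fetal LPS responses, tissue, age and how LPS reached the cells cannot be separated by design. In adult cells, interferon-induced genes stood far higher than at PBS, and primary granule genes stood lower. Cxcl10, a chemokine induced by interferon (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), was at 2515 CPM (2506 to 2525) after LPS and 1.32 CPM (1.14 to 1.52) at PBS, a 1907-fold ratio. Isg15, a ubiquitin-like protein induced by type I interferon (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), was at 1727 against 15.4 CPM, 112-fold higher (107 to 117). In wild-type fetal cells the same interval moved few genes far: Cxcl10 stayed below 1 CPM in every fetal library, and the largest ratios belonged to Pf4, Trnp1 and the neutrophil granule gene Camp.

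Among the type I interferon genes measured in adult cells, 31 of 32 stood at least 2-fold higher at 3 h and 0 lower, with a median log2 ratio of 3.58. They included Rsad2, an antiviral enzyme (log2 6.86), Ifit1, which binds foreign RNA (6.54), and Usp18, a brake on interferon signalling (5.16). Of the interferon-gamma genes, 21 of 28 were at least 2-fold higher and 0 lower (median 2.68), with the immunity-related GTPase Iigp1 at 5.94 and the guanylate-binding proteins Gbp5 at 4.74 and Gbp2 at 4.54. The acute NF-kB list had 16 of 27 members at least 2-fold higher (median 1.17, or 1.93 with 1 CPM added and 1.91 in HSC and multipotent progenitor-like cells), among them the chemokine Ccl4 (3.23), the transcription factor Irf1 (2.82) and the NF-kB subunit Relb (2.74). STAT3 and acute-phase targets had 7 of 17 higher and 1 lower (median 0.73). That list's acute-phase protein Saa3 was at 441 against 0.477 CPM, its iron-binding protein Lcn2 at 103 against 12.6 CPM, and its cytokine signalling inhibitor Socs3 had a log2 ratio of 1.76. Each of these 4 medians stood at percentile 100 of 10000 random lists matched on expression. Ccl5, a chemokine outside the lists, was 271-fold higher (log2 6.91), and the stem-cell antigen gene Ly6a had a log2 ratio of 3.28. The T-cell protease gene Gzmb (2.13), the stress factor Atf3 (2.33), the cell-cycle inhibitor Cdkn1a (1.35) and the Toll-like receptor adaptor Myd88 (1.09) were higher too.

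Primary granule genes of early neutrophils were lower in adult cells at 3 h, with 9 of 16 at least 2-fold lower (median −1.5, percentile 0 of the random lists). Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215), was at 674 against 2732 CPM, and the proteinase gene Prtn3 at 772 against 3057 CPM. Neutrophil progenitor-like cells made up 4.55% of that library against 11.5% at PBS, and with class shares set equal the primary granule median was −0.43. Cebpe, a transcription factor of granule formation, had the lowest ratio of all named genes in this comparison (log2 −2.25, 7.37 against 53.9 CPM). Lower levels also held for the lectin receptor Clec12a (−2.09), the monocyte gene F13a1 (−2.02), the myeloid transcription factors Irf8 (−1.47) and Gfi1 (−1.45), the lymphoid enzyme gene Dntt (−1.74), the stem-cell factor Hlf (−1.68) and Cd34 (−1.39). Monocyte progenitor-like cells made up 4.12% of that library against 10.7% at PBS. Secondary granule genes had a median of −0.99, with 4 of 9 at least 2-fold lower and 2 higher, but 0.37 with class shares set equal. Within HSC and multipotent progenitor-like cells alone, Cxcl10 had a log2 ratio of 9.75, the NF-kB inhibitor Nfkbia 3.25 and Lcn2 2.99, while Dntt was at −2.49. That class joins clusters 0 and 1, and cluster 1 held 61.2% of it at PBS and 63.6% at 3 h in adult cells.

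In wild-type fetal cells at 3 h, 0 of 24 type I interferon genes, 0 of 13 interferon-gamma genes and 0 of 12 NF-kB genes reached a 2-fold ratio in either direction. Their medians were 0.14 (percentile 100 of random lists), 0.05 and −0.00. The platelet chemokine Pf4 was at 53.9 against 9.60 CPM (log2 2.01), Trnp1 at 38.8 against 8.76 CPM and Camp, an antimicrobial peptide of secondary granules, at 81.5 against 25.3 CPM. Secondary and tertiary granule genes had a median of 0.53, with 3 of 11 at least 2-fold higher and 0 lower, and S100a9, a calcium-binding alarmin of neutrophils, at 456 against 193 CPM. With class shares set equal that median was 0.30 and 0 members reached 2-fold, and maturing neutrophil-like cells made up 1.32% of the library against 1.06% at PBS. Lower genes included Rsrp1 (log2 −1.21), the histone transcript Hist1h2ap (−1.03) and the chaperone Hspa8 (−0.93). The difference between adult and fetal type I interferon medians was not tested, since each group had 1 library. TMM scaling shifted the median of all genes in the adult 3 h ratio from −0.09 to 0.06.

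**Figure D1:**
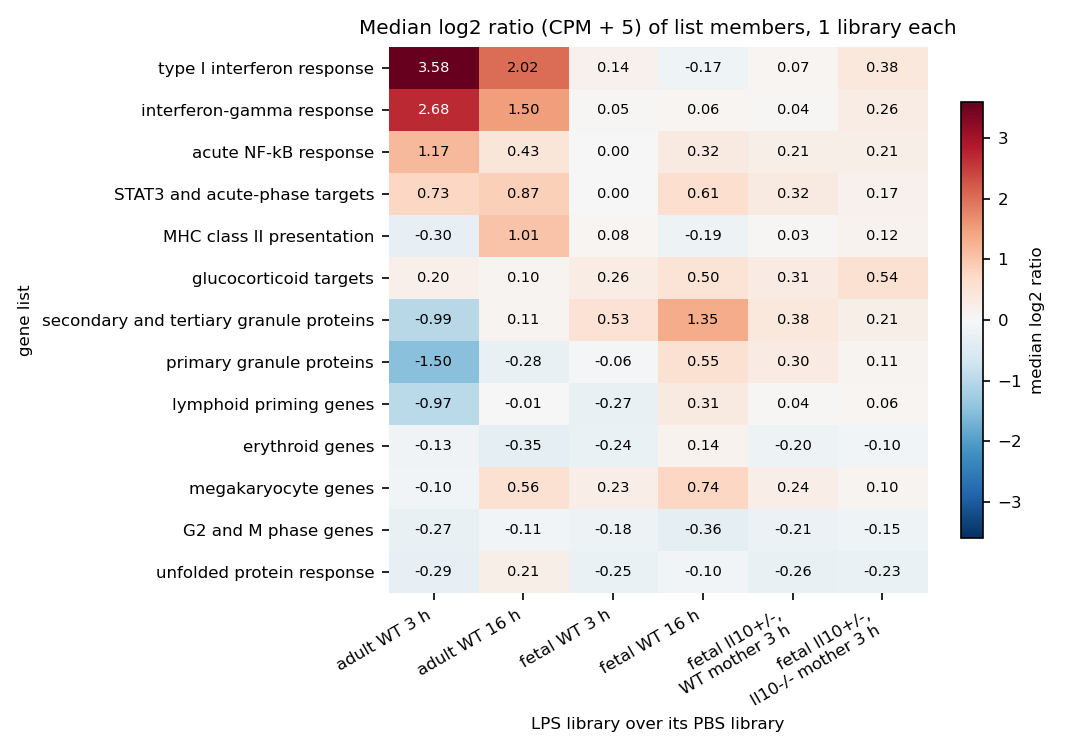
Median log2 ratio of gene lists (rows) in the LPS ratios of adult, wild-type fetal and Il10+/- fetal cells (columns), 1 library against 1. Medians are shown as colour and printed value, in log2 of CPM with 5 added. The adult type I interferon median at 3 h lies at 3.58, and the 3 fetal medians at 3 h lie between 0.07 and 0.38.

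At 16 h the question is whether the response lasts and whether fetal cells join it. Both 16 h files came from Cell Ranger 7.0.1 and their PBS partners from 5.0.1, per the file headers. Genes in the top quartile of intron length stood above those in the bottom quartile by 1.02 in the adult ratio and 0.88 in the fetal ratio, against 0.05 and −0.09 at 3 h. Kcnq5, with 555851 bp of introns, was among the largest ratios in both (5.29 and 4.64), as were Lrmda, Arl15 and Mir142hg. TMM scaling moved the median of all genes from 0.22 to −0.29 in the adult and from 0.02 to −0.39 in the fetal 16 h ratio. List values at 16 h are therefore led by members with at most 5000 bp of introns, taken relative to all such genes, a choice made after the data were seen.

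**Figure D2:**
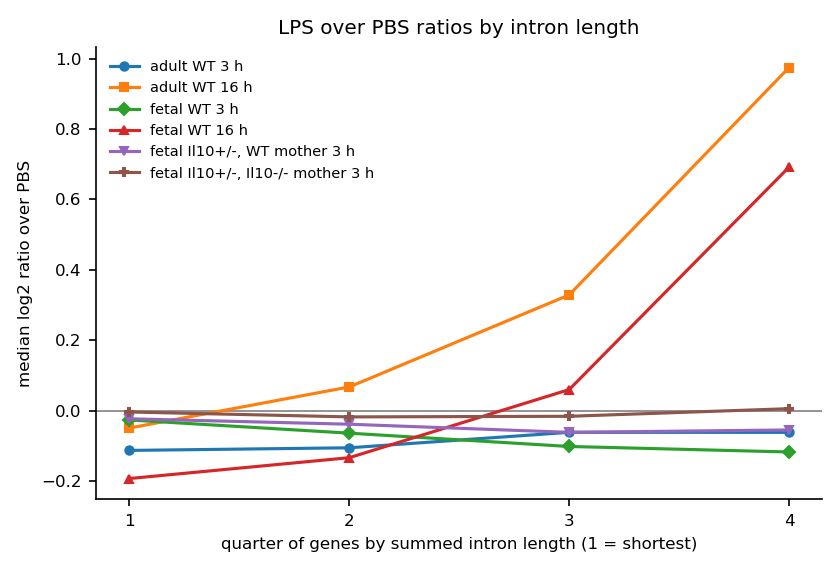
Median log2 ratio over PBS (vertical axis) of genes in quartiles of summed intron length (horizontal axis), by comparison. The gap between the top and bottom quartiles is 1.02 and 0.88 in the 16 h ratios and between −0.09 and 0.05 in the 3 h ratios.

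Adult cells at 16 h still held interferon-induced genes above PBS. Among short-intron members, the type I interferon median was 2.20 above all short-intron genes, with 5 of 6 at least 2-fold higher, and the interferon-gamma median 1.45 above, with 12 of 14 higher. Over all members the 2 medians were 2.02 and 1.5, with 27 of 31 and 24 of 26 at least 2-fold higher. Isg15 was at 177 CPM against 15.4 at PBS, Irf7, a master regulator of interferon genes, had a log2 ratio of 3.71, and the chemokine Cxcl9 one of 3.04. Cxcl10 was at 38.8 CPM. Cd74, the invariant chain of MHC class II, was at 242 against 2.04 CPM, having stood at 26.6 CPM at 3 h, and the class II genes H2-Eb1 and H2-Aa had log2 ratios of 3.74 and 3.56. The MHC class II list had 5 of 10 members at least 2-fold higher and a median of 1.01, or 0.17 over its 3 short-intron members relative to all such genes. Primary granule genes stayed lower, at −0.94 for short-intron members and −0.28 over all members, with Elane at 551 CPM, the myeloperoxidase gene Mpo at −1.18 and Irf8 at −1.40. Pf4 was at 21.3 against 171 CPM, and the linker histone genes Hist1h1e and Hist1h1b were at −2.67 and −2.42. Acute-phase Lcn2 (2.54) and Saa3 (4.25) stayed above PBS, and the NF-kB median was 0.50 for short-intron members.

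Wild-type fetal cells at 16 h held more transcripts of neutrophil granule genes than at PBS and no higher type I interferon list. This library stood apart in its median mitochondrial share, 4.89% against 2.49% to 3.22% in the others, and 2056 of its 3734 cells were within 5%. Short-intron secondary and tertiary granule genes had a median 2.64 above all short-intron genes, with 6 of 8 at least 2-fold higher, and over members at 5 CPM or more the median was 1.35 with 8 of 11 higher and 0 lower (percentile 100 of random lists). Over all members with at least 1 UMI it was 0.60. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) was at 1592 against 193 CPM, 8.23-fold higher (8.13 to 8.33), and its partner S100a8 was 7.42-fold higher. Lcn2 was at 54.5 against 3.34 CPM, and Ngp, a granule protein of maturing neutrophils, at 31.2 against 0.676 CPM. Primary granule genes were 0.69 above, with Ms4a3 at 1.09 and the lysozyme gene Lyz2 at 0.89, and myeloid transcription factors 0.84 above, with Cebpb, a driver of emergency granulopoiesis, at 1.04. STAT3 targets had a short-intron median of 1.24, with 5 of 9 at least 2-fold higher. That list shares Lcn2, Hp, Chil3, S100a8 and S100a9 with the secondary granule list, so these lists are not independent. NF-kB genes had a short-intron median of 0.54, with 0 of 7 at 2-fold. The type I interferon median was −0.044 over 5 short-intron members and −0.17 over all measured members, or −0.42 with TMM scaling and −0.48 in neutrophil progenitor-like cells, with Isg20 at −0.80 and Bst2 at −0.75. The glucocorticoid-induced genes Zbtb16 (2.19), Tsc22d3 (1.37) and Fkbp5 (1.03), with 176643, 56791 and 108966 bp of introns, were higher, and the chaperone Hsph1 (−1.71) and the mitotic gene Cenpf (−1.06) lower. The 6 short-intron glucocorticoid targets had a median 0.51 above all short-intron genes, with 0 at 2-fold. Within neutrophil progenitor-like cells alone, S100a9 was 4.61-fold higher (2025 against 439 CPM) and Lcn2 had a log2 ratio of 2.03, although the secondary granule median in that class was 0.34, against 0.70 with class shares set equal.

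Adult and fetal progenitors also differed at PBS, where tissue and age cannot be separated by design. Adult cells held more transcripts of the interferon-gamma and primary granule lists. Fetal cells held more of the fetal growth programme. H2-Q7, a class Ib MHC gene (chromosome 17, 35439155 to 35443773), was at 89.8 CPM in adult and 0.0468 CPM in fetal cells, and the classical MHC class I genes H2-K1 and H2-D1 had log2 ratios of 2.41 and 2.26. The interferon-gamma list, which holds these genes, had a median of 1.11 with 9 of 16 at least 2-fold higher in adult cells and 0 lower, and a median of 0.47 over all members with at least 1 UMI. Of the primary granule genes, 11 of 16 were at least 2-fold higher in adult cells (median 1.26), among them Elane (1.96), Clec12a (1.77) and Ms4a3 (1.61). That median was 0.36 with class shares set equal and 0.16 within neutrophil progenitor-like cells. Secondary granule genes went both ways: 4 of 11 were at least 2-fold lower in adult cells and 2 higher, with S100a9 at 5.97 against 193 CPM, Camp at 0.332 against 25.3 CPM and a list median of 0.48. Fos (2.15), Fosb (2.14) and Jun (1.88), immediate early genes also induced when tissue is dissociated, were higher in adult cells, and 7 of 17 members of their list were at least 2-fold higher and 0 lower (median 0.76).

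The fetal progenitor programme had 6 of 10 members at least 2-fold lower in adult cells and 0 higher, with a median of −1.27 (percentile 0 of random lists). Igf2bp3, an RNA-binding protein of fetal cells, had a log2 ratio of −2.47, and the chromatin protein gene Hmga2 one of −1.96. In HSC and multipotent progenitor-like cells alone, Dlk1 was 64.8-fold lower in adult cells (0.724 against 47.0 CPM), Hmga2 at 40.9 against 255 CPM and Lin28b, a regulator of fetal haematopoiesis, at 0.0852 against 20.9 CPM. Dntt, which adds bases to rearranging antigen receptor genes, was at 123 CPM in adult and 0.211 CPM in fetal cells of that class. Most of the class was cluster 1 in the adult library (61.2%) and cluster 0 in the fetal library (55.9%). Stfa1, a cysteine protease inhibitor, was at 191 CPM in all fetal cells and had 1 UMI in adult cells, and Cstdc5, of the same family, was at 86.8 CPM in fetal cells and had 0 UMIs in adult cells. Pf4 (3.6), the carbonic anhydrase gene Car1 (3.19) and the protease inhibitor gene Slpi (3.12) were higher in adult cells, and Ndufa4l2 (−5.30), Fabp5 (−2.96) and the metallothionein gene Mt2 (−2.80) lower.

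**Figure D3:**
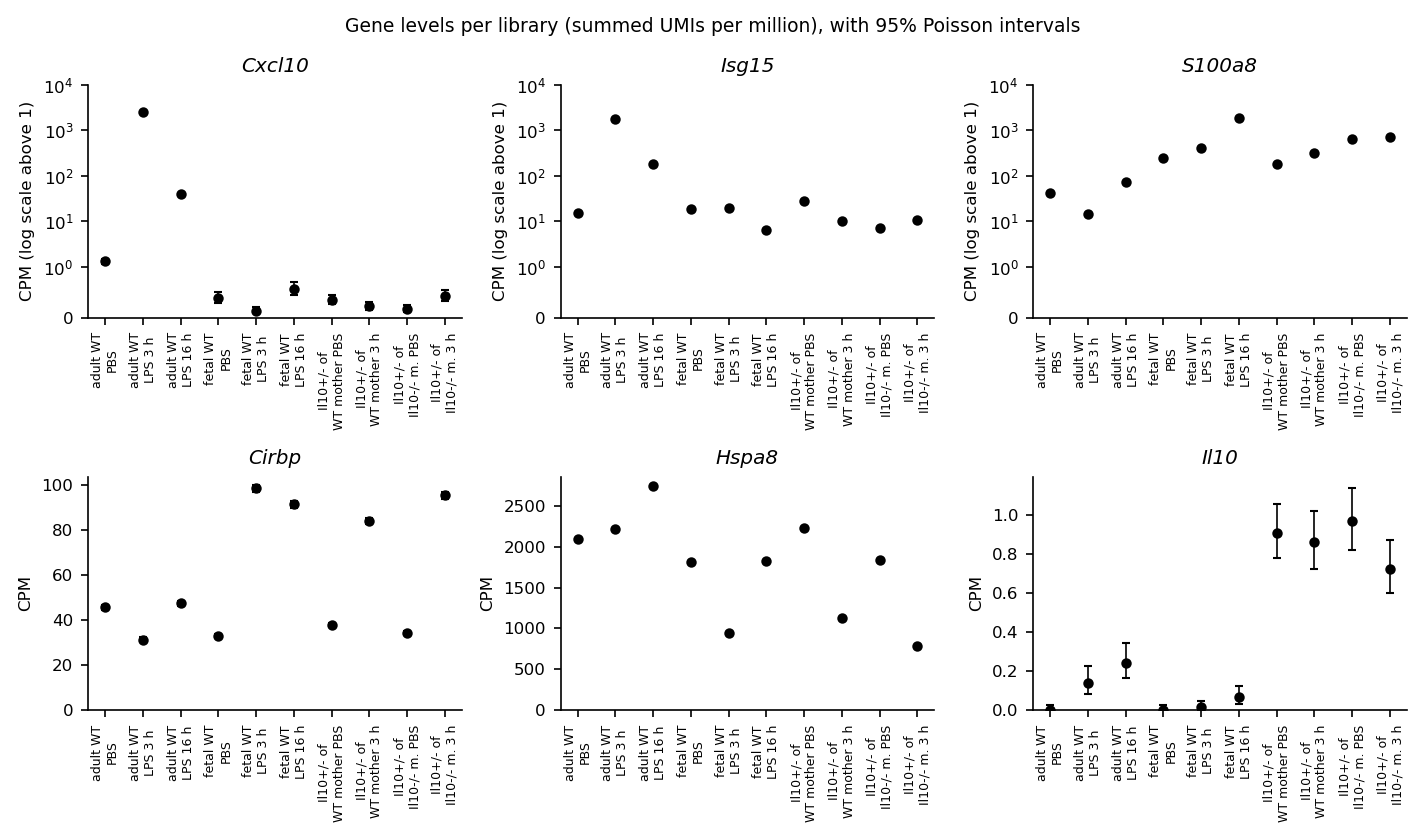
Levels in CPM (vertical axis) of Cxcl10, Isg15, S100a8, Cirbp, Hspa8 and Il10 in each of the 10 libraries, with exact 95% Poisson intervals. The axis is logarithmic above 1 CPM for Cxcl10, Isg15 and S100a8 and linear for the other genes. Isg15 reaches 1727 CPM in adult cells at 3 h, and Il10 stays below 1 CPM in all 10 libraries.

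LPS at 3 h against PBS was the only contrast with independent repeats, 1 pair of libraries in each of 3 fetal litter types: wild-type fetuses, Il10+/- fetuses of wild-type mothers and Il10+/- fetuses of Il10-/- mothers. Genes rising across the pairs included Cirbp and Camp, and genes falling included Hspa8. Cirbp, a cold-inducible RNA-binding protein (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786), rose from 34.8 to 92.5 CPM, a log2 change of 1.42 ± 0.08 (moderated SE of the edgeR fit; edgeR adjusted p = 3.13e-05). Hspa8, a constitutive heat-shock chaperone (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087), fell from 1965 to 955 CPM (log2 −1.04 ± 0.08, edgeR adjusted p = 1.19e-04). Camp rose from 23.9 to 63.2 CPM (log2 1.45 ± 0.10, edgeR adjusted p = 9.58e-05). All 3 genes moved the same way in 3 of 3 pairs, which the naming rule required of each gene named for this test.

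With edgeR, 1427 genes rose and 1605 fell out of 14881 tested at an adjusted p of 0.05, and 3003 of these 3032 had the same sign in all 3 pairs. The changes were mostly small, with 735 genes at 1.5-fold or more. The count rests on the litter block, since the same test without it called 43 genes, and on 2 of the pairs, since it was 1317 without the pair of wild-type mothers and 1025 without the pair of Il10-/- mothers. DESeq2 with the same block called 2439 genes, of which 2368 were shared. The other large rises were in Trnp1 (log2 1.70), Pf4 (1.33), the stefin genes Cstdc4 (1.26), Cstdc5 (0.93) and Stfa1 (0.72), S100a9 (0.92, from 229 to 403 CPM), N4bp2l1 (0.82) and the stress-response gene Ier3 (0.77). The other large falls were in Rsrp1 (−1.17), Hsph1 (−0.87), the splicing factor gene Luc7l (−0.82), Mns1 (−0.72), Zfp322a (−0.72), the S-phase cyclin gene Ccne1 (−0.70), the corepressor gene Cbfa2t3 (−0.64), the transferrin receptor gene Tfrc (−0.63) and the endoplasmic reticulum chaperone Hspa5 (−0.62). Pf4 varied between pairs, with log2 ratios of 2.01, 0.91 and 0.40. Across 7016 genes, which are not independent replicates, the LPS ratios of the 3 pairs, which share no library, correlated with Pearson r of 0.575, 0.598 and 0.690 (Spearman 0.551, 0.569 and 0.663).

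**Figure D4:**
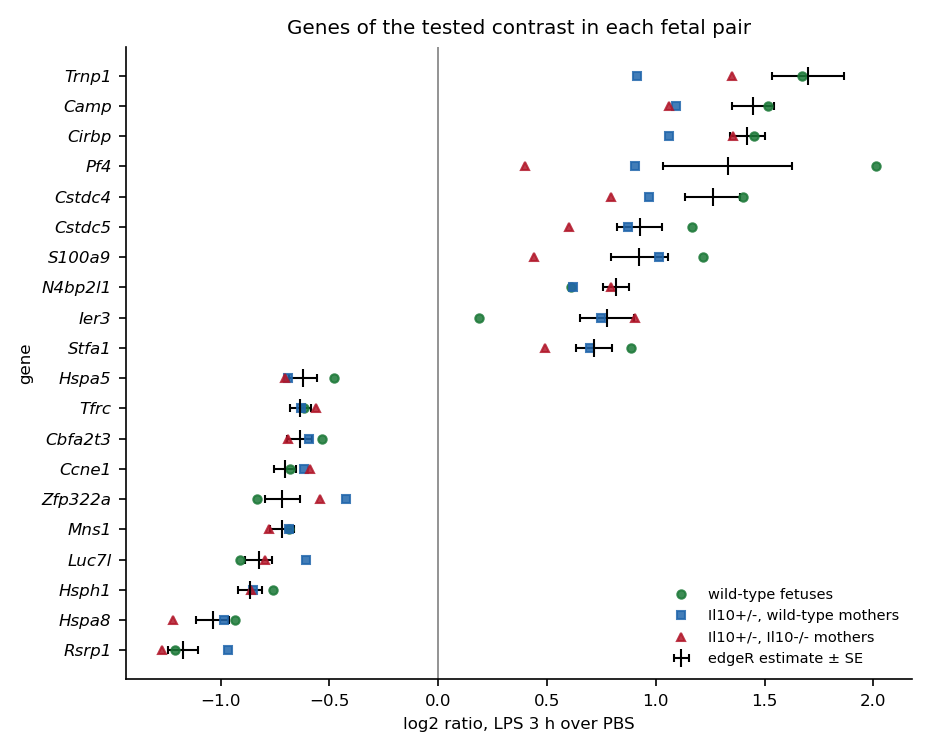
Log2 ratio of LPS at 3 h over PBS (horizontal axis) of the 20 genes with the largest tested changes, with 1 point per fetal litter type and a bar for the fitted change and its standard error. Every point lies on the same side of 0 as its fitted value, as the rule that chose the genes required. Pf4 has the widest spread, from 0.40 to 2.01.

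Members of the interferon, NF-kB and STAT3 lists rose in fetal cells with list medians of 0.14 to 0.30, and none was called lower. Of 32 type I interferon genes tested, 15 rose and 0 fell, or 19 and 0 adjusted over the list alone. Their median log2 change was 0.30, with Lgals3bp at 0.50. Over members at 5 CPM or more, the pair medians were unequal. They were 0.14 in wild-type fetuses, 0.07 with wild-type mothers and 0.38 with Il10-/- mothers. Interferon-gamma genes had 8 of 26 rising and 0 falling, and 8 and 0 adjusted over the list alone, including the proteasome subunits Psmb9 (0.29) and Psmb8 (0.24), the MHC class I light chain B2m (0.27) and H2-D1 (0.20). NF-kB genes had 9 of 29 rising and 0 falling by either adjustment, with Ier3 at 0.77 and Nfkbia at 0.65. STAT3 and acute-phase targets had 11 of 23 rising and 0 falling (12 and 0 adjusted over the list alone). Among them were S100a9 at 0.92, S100a8 at 0.58 and Cebpb at 0.24. S100a8, S100a9, Lcn2, Hp and Chil3 also belong to the secondary granule list, so these lists are not independent. In limma's camera test with a preset correlation these 4 lists had adjusted p values of 5.09e-07, 0.00206, 0.00512 and 7.41e-06. With an estimated correlation the adjusted p values were 0.53, 0.48, 0.52 and 0.48.

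The secondary granule, megakaryocyte and glucocorticoid lists had more rising than falling members. Secondary and tertiary granule genes had 9 of 16 rising and 0 falling (10 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 3.41e-05, and adjusted p = 0.48 with an estimated correlation). The medians in the pairs of wild-type fetuses, wild-type mothers and Il10-/- mothers were 0.53, 0.38 and 0.21, or 0.30, 0.19 and 0.10 with class shares set equal. Neutrophil progenitor-like cells made up 6.68%, 5.47% and 7.60% at PBS and 6.24%, 7.03% and 8.22% at LPS. Maturing neutrophil-like cells made up 1.06%, 0.755% and 1.40% at PBS and 1.32%, 0.887% and 1.35% at LPS. For Il10-/- mothers, the low-UMI cluster 14 held 613 cells at LPS against 99 at PBS, which lowers all other shares at LPS. Their maturing neutrophil-like cells numbered 72 at LPS and 68 at PBS, so the fall from 1.40% to 1.35% cannot be read as a loss. Mature neutrophil genes had 3 of 9 rising (3 and 0 adjusted over the list alone; camera adjusted p = 0.00648, and adjusted p = 0.48 with an estimated correlation). Primary granule genes had 2 rising and 1 falling of 16 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00534, and adjusted p = 0.65 with an estimated correlation), with Ctsg at 0.28 and the chaperone Calr at −0.24. Megakaryocyte genes had 10 of 16 rising and 0 falling (11 and 0 adjusted over the list alone; camera adjusted p = 8.62e-06, and adjusted p = 0.48 with an estimated correlation). Megakaryocyte progenitor-like cells made up 2.93%, 4.83% and 4.02% at PBS and 4.27%, 5.43% and 3.36% at LPS in wild-type fetuses and the litters of wild-type and Il10-/- mothers. Glucocorticoid targets had 12 of 18 rising and 0 falling, or 13 and 0 adjusted over the list alone. Those rising included Tsc22d3 (0.71), Fkbp5 (0.45) and Zfp36l2 (0.44). The list median was 0.47, with camera adjusted p = 3.53e-09, and camera adjusted p = 0.48 with an estimated correlation.

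The erythroid, cell-cycle and unfolded protein lists had more falling than rising members. Erythroid genes had 12 of 24 falling and 4 rising (14 and 4 adjusted over the list alone; camera adjusted p = 4.01e-04, and adjusted p = 0.48 with an estimated correlation), with the erythroid transcription factor genes Klf1 at −0.61 and Tal1 at −0.37, and Car1 rising by 0.64. Late erythroid-like cells made up 11.0%, 5.47% and 9.37% at PBS and 9.53%, 3.84% and 7.85% at LPS in wild-type fetuses and the litters of wild-type and Il10-/- mothers. G2 and M phase genes had 13 of 24 falling and 0 rising (17 and 0 adjusted over the list alone; camera adjusted p = 5.09e-07, and adjusted p = 0.48 with an estimated correlation), including the mitotic kinases Aurka (−0.49) and Plk1 (−0.37). S phase genes had 6 of 24 falling and 0 rising by either adjustment (camera adjusted p = 0.0283, and adjusted p = 0.52 with an estimated correlation), including Hells (−0.34) and Cdc6 (−0.27). The unfolded protein response had 13 of 22 falling and 0 rising (14 and 0 adjusted over the list alone; median −0.23, camera adjusted p = 5.09e-07, and adjusted p = 0.48 with an estimated correlation), with the stress transcription factor Xbp1 at −0.59, Creld2 at −0.55 and Herpud1 at −0.45.

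The other 15 lists did not pass camera with the preset correlation, with limma's adjusted p values from 0.0569 to 0.976. Counts of rising and falling genes were 3 and 1 of 19 for myeloid transcription factors (Irf8 at −0.47), 4 and 0 of 20 for stem cell genes (Txnip at 0.70), 0 and 2 of 18 for lymphoid priming (Bcl11a at −0.23), 3 and 1 of 14 for basophil and mast cell genes (Gata2 at −0.25) and 6 and 0 of 21 for cytokine receptors (Ifngr1 at 0.29). They were 2 and 1 of 21 identifiers for the 20 glycolysis genes, Aldoa being counted under 2 of them, 1 and 0 of 27 for the respiratory chain, 5 and 4 of 20 for immediate early and dissociation stress genes, the 4 falling being the heat-shock genes Hspa1a, Hspa1b, Hsph1 and Dnajb1, 2 and 0 of 16 for the fetal programme, 3 and 1 of 20 for LPS sensing and 1 and 0 of 9 for MHC class II. For other cell types they were 1 and 0 of 11 for hepatocytes, 1 and 1 of 10 for macrophages, 1 and 0 of 5 for endothelial and stromal cells and 2 and 0 of 8 for T and NK cells. The immediate early and dissociation stress list had a median of 0.09 but a mean of −0.50, the MHC class II list 0.14 and −0.10, the fetal programme −0.02 and 0.02, and LPS sensing −0.03 and 0.04. Camera called 13 of the 28 lists with the preset and 0 with the estimated correlation (lowest adjusted p = 0.48). Limma's fry, which asks whether a list's genes move one way on balance, called 0 (lowest adjusted p = 0.106), and in either direction 19.

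Within cell classes, the test called most genes in early erythroid progenitor-like cells, with 1542 rising and 1542 falling, and 698 and 720 in HSC and multipotent progenitor-like cells. Counts depend on the number of cells in a class. In the HSC-like class, where cluster 0 held 51.7% to 57.0% of cells in each of the 6 libraries, Cirbp rose from 73.1 to 193 CPM, Ier3 from 28.7 to 72.7 CPM and the serine kinase gene Pim1 from 169 to 287 CPM. The feedback regulator Zfp36 and the AP-1 subunit gene Junb both rose by 0.95 in that class, and Hsph1 fell by 1.2. Neutrophil progenitor-like cells had 403 rising and 417 falling genes, with Ier3 at 1.40 and Pim1 at 0.80. Monocyte progenitor-like cells had 125 and 131, with Pim1 from 80.9 to 279 CPM, Junb at 1.26 and Zfp36 at 1.22. In megakaryocyte progenitor-like cells, with 297 and 245, Pf4 rose from 522 to 1105 CPM. Late erythroid-like cells had 560 and 525, lymphoid-primed cells 148 and 137, basophil and mast cell progenitor-like cells 157 and 105, and the unnamed cluster 7 had 271 and 250.

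The maternal comparison asks how Il10+/- fetuses respond to LPS when the mother lacks or carries functional Il10. In both litter types Cirbp, Trnp1 and Camp stood higher at 3 h and Rsrp1, Hspa8 and Hsph1 lower. Interferon genes differed more between the litters at PBS than in either LPS response. Isg15 was at 27.7 CPM at PBS and 9.96 at LPS in fetuses of wild-type mothers (log2 −1.13), and at 7.2 CPM at PBS in fetuses of Il10-/- mothers. The type I interferon median was 0.07 in the LPS ratio of wild-type mothers (bootstrap interval over members 0.02 to 0.17) and 0.38 in that of Il10-/- mothers (0.25 to 0.43), and the median of the member-by-member differences was 0.21 (0.18 to 0.32). That difference was 0.39 with 1 CPM added in place of 5, 0.37 in HSC and multipotent progenitor-like cells and 0.15 in neutrophil progenitor-like cells, where the median for Il10-/- mothers was −0.0068. Bst2, which tethers viruses to the cell surface, had LPS ratios of −0.35 and 0.41, and Zfp36l2 0.25 and 0.73. Each LPS ratio lies within 1 Cell Ranger version, and with 1 library per group the difference between the mothers was not tested.

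In HSC and multipotent progenitor-like cells of fetuses of Il10-/- mothers, Socs3, an inhibitor of cytokine signalling, was at 23.8 CPM (21.7 to 26.1) after LPS and 1.72 at PBS, 13.8-fold higher (9.67 to 20.5). In the litter of wild-type mothers it was at 19.5 and 2.18 CPM, and in wild-type fetuses at 10.9 and 3.27 CPM. Ier3 was at 85.7 against 25.5 CPM in that class for Il10-/- mothers and 73.8 against 29.4 for wild-type mothers. The chemokine Ccl4 was at 64.0 against 21.8 CPM for Il10-/- mothers and 51.8 against 34.9 for wild-type mothers. Isg15 was at 42.6 against 28.0 CPM for Il10-/- mothers and 34.5 against 106 for wild-type mothers. The type I interferon median of the wild-type mothers' LPS ratio was −0.034 in this class, opposite in sign to that of all cells. Glucocorticoid targets had all-cell medians of 0.31 and 0.54 for wild-type and Il10-/- mothers, NF-kB genes 0.21 in both, and secondary granule genes 0.38 and 0.21.

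Only 7 genes stood at least 2-fold higher and 4 at least 2-fold lower in the wild-type fetal pair, the separate pair used to choose genes. The 7 had median ratios of 0.97 for wild-type and 0.79 for Il10-/- mothers, and the median difference of Il10-/- less wild-type mothers was −0.18. For the 4 lower genes the medians were −0.41 and −0.17, with a difference of 0.20. Other settings chose other sets, with differences of 0.36 for the 3 higher genes left with class shares set equal and −0.35 for the 3 lower genes left with TMM scaling. Among 148 genes at least 2-fold higher in adult cells at 3 h and at 5 CPM or more in any Il10+/- library, of 210 at 2-fold without that limit, 45.9% had a positive ratio in wild-type fetal cells, 57.4% with wild-type mothers and 81.8% with Il10-/- mothers. With TMM scaling, 182 genes were chosen and these shares were 59.3%, 59.9% and 74.7%. Of the 132 lower genes chosen alike, of 135 without the limit, 75.8%, 15.2% and 29.5% had a negative ratio in the same 3 pairs, and of the 30 chosen with class shares set equal, 80.0%, 60.0% and 53.3%. The medians of all genes at 20 CPM or more also differed between the pairs, at −0.079, −0.043 and −0.0080.

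Between the mothers at PBS, fetuses of Il10-/- mothers had lower interferon genes. The type I interferon median was −0.67 (−0.87 to −0.48), with 4 of 24 at least 2-fold lower and 0 higher, and Rtp4, an interferon-induced chaperone, was at 5.26 against 24.2 CPM. Interferon-gamma genes had a median of −0.48, with the GTPase Irgm1 at −1.55 and the class Ib gene H2-T23 at −1.43. Secondary and tertiary granule genes had a median of 0.48, with 4 of 9 at least 2-fold higher and 0 lower, and S100a8 was at 644 against 177 CPM, Camp at 37.1 against 9.21 CPM and Fcnb at 27.5 against 9.99 CPM. That median was 0.081 with class shares set equal and 0.12 in neutrophil progenitor-like cells, and these made up 7.60% against 5.47% and maturing neutrophil-like cells 1.40% against 0.755% of the libraries. The 3 all-cell medians at LPS were −0.43, −0.45 and 0.21. Files of Il10-/- mothers came from Cell Ranger 6.1.2 and those of wild-type mothers from 5.0.1, so mother and software version cannot be told apart in these ratios. The largest ratios at PBS belonged to histone transcripts, with Hist1h2ap at 3.93 and Hist1h2ae at 2.72, and to Gstp1 (2.40). The mast cell protease genes Tpsb2 (−2.42) and Cma1 (−2.30) were lowest, at 36.0 and 35.0 CPM in the PBS library of wild-type mothers. Both are top genes of the unnamed cluster 18, which held 28 cells of that library and 7 of the PBS library of Il10-/- mothers.

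Clustering of all 10 libraries gave 20 clusters, of which 16 were given 11 names and 4 were left unnamed. All shares are of kept cells within the lineage-negative, c-Kit-positive gate. Neutrophil progenitor-like cells made up 11.5% (10.8 to 12.3) of the adult PBS library, 4.55% (3.97 to 5.19) at 3 h of LPS and 8.00% at 16 h. The difference at 3 h was −58.0 percentage points when libraries were clustered without correction. The class of that name then covered other cells, since its main share at PBS was 11.5%. Monocyte progenitor-like cells followed with 10.7%, 4.12% and 6.91%, and early erythroid progenitor-like cells made up 19.3%, 30.3% and 18.9%. In wild-type fetal libraries, neutrophil progenitor-like cells made up 6.68% (6.00 to 7.41) at PBS, 6.24% at 3 h and 9.29% (8.38 to 10.3) at 16 h, and maturing neutrophil-like cells 1.06% (0.80 to 1.39), 1.32% and 3.72% (3.14 to 4.38). HSC and multipotent progenitor-like cells made up 19.9% (18.8 to 21.0), 17.4% and 14.6% (13.5 to 15.8) of the same libraries. Neutrophil progenitor-like cells made up 5.47% at PBS and 7.03% at LPS for wild-type mothers, and 7.60% and 8.22% for Il10-/- mothers. All shares of the LPS library of Il10-/- mothers are lowered by its 613 cells of the low-UMI cluster 14, against 99 at PBS. The fetal 16 h differences in neutrophil progenitor-like and HSC-like shares did not keep their sign when libraries were clustered without correction between them, where the neutrophil difference was −9.16 percentage points and the HSC difference 0. That 0 cannot be read as an unchanged share, since the HSC-like name may have held no cells of these libraries there. With a stricter limit on mitochondrial transcripts the neutrophil and HSC differences were 6.71 and −1.01 points. The maturing neutrophil-like class was named neither at resolution 0.4 nor at 1.2. Without correction its difference was 37.4 points, and both neutrophil names there covered other cells than in the main clustering.

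**Figure D5:**
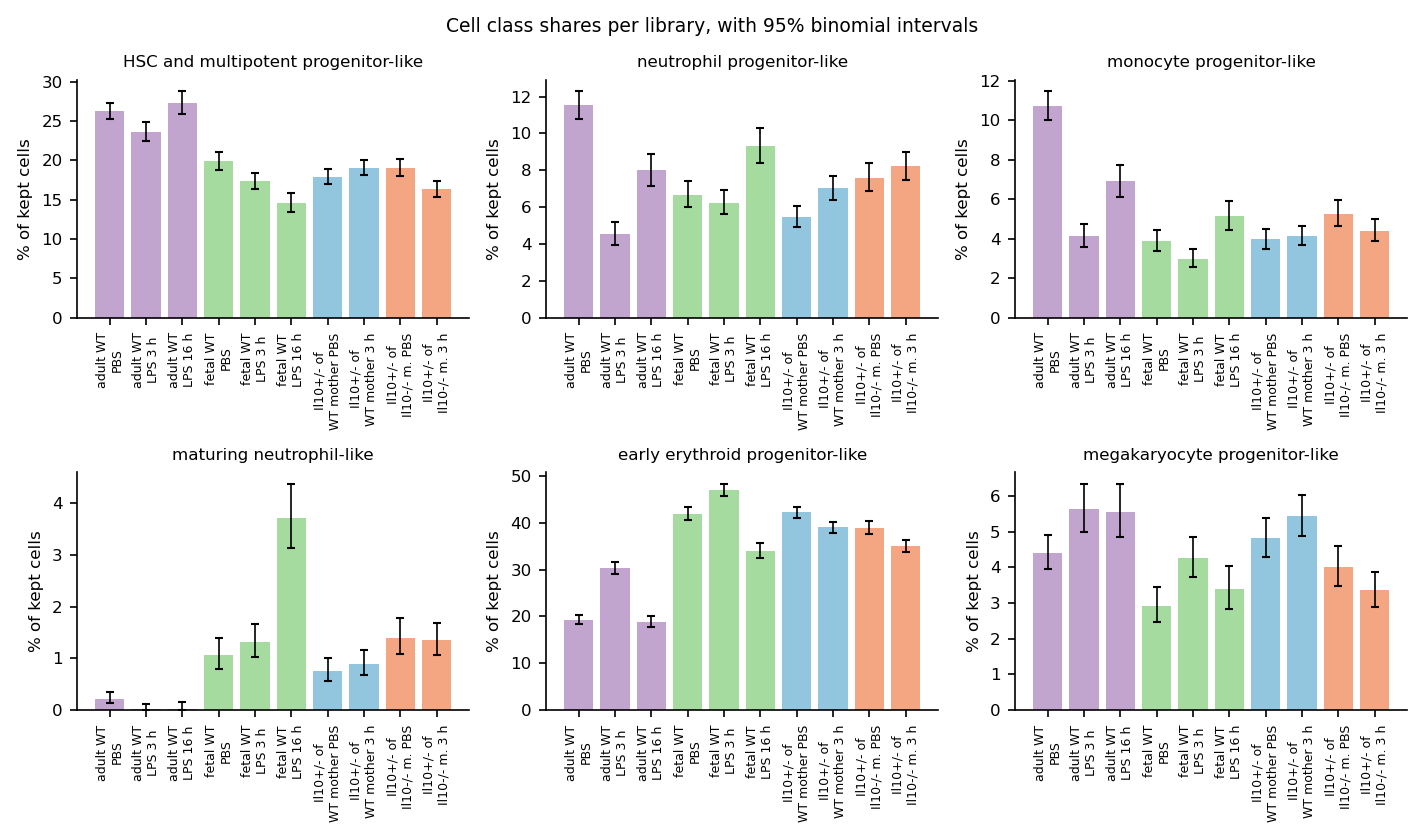
Share of kept cells (percent, vertical axis) for the 10 libraries, with exact 95% binomial intervals. The classes shown are HSC-like, neutrophil progenitor-like, monocyte progenitor-like, maturing neutrophil-like, early erythroid progenitor-like and megakaryocyte progenitor-like. Neutrophil progenitor-like cells fill 11.5% of the adult PBS library and 4.55% at 3 h, and 6.68% of the wild-type fetal PBS library and 9.29% at 16 h.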

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

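The tests on intron length and on interferon genes between the mothers were chosen only after the result was seen, and those on heat-shock genes and on other splits of the libraries were chosen before.

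The 2 lists flagged here had adult and fetal wild-type medians of opposite sign and far apart, 1 of them only without adjustment for the mix of classes. Opposite signs also occurred elsewhere, as for short-intron primary granule genes at 16 h relative to all short-intron genes. At 3 h, the secondary and tertiary granule median was −0.99 in adult and 0.53 in fetal cells, and the median of the member-by-member differences was −1.19. With class shares set equal these were 0.37, 0.30 and −0.35, so the opposite signs were not kept. Neutrophil progenitor-like cells made up 4.55% of the adult library against 11.5% at PBS, and 6.24% against 6.68% in fetal cells. At 16 h, the type I interferon median was 2.02 in adult and −0.17 in fetal cells, with a median difference of 2.08. For short-intron members, relative to all short-intron genes, the fetal median was nearer to no change, as given above. Each group had 1 library, and neither difference was tested. The library of Il10-/- mothers at LPS held 1418 barcodes under 1000 UMIs, against 18 to 174 in the other 9. These barcodes entered only the alternative with all deposited barcodes.

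Long genes stood higher in both 16 h libraries. The smaller of the 2 gaps between top and bottom quartiles of intron length was 0.88 (fetal), where the gaps at 3 h lay between −0.09 and 0.05. A late response of long genes that scales with the interferon response is argued against: the adult and fetal gaps differed by 0.14, although their type I interferon medians differed by 2.19. Counting of intronic reads by Cell Ranger 7.0.1, which made both 16 h files, is a candidate explanation and stays open, since the gap of 0.88 is the pattern itself and tests nothing further. It cannot be told apart from a late effect of LPS shared by both tissues, because no 16 h file came from the version of its PBS partner.

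Cirbp and Rbm3, the cold-inducible genes, were higher and heat-shock genes lower at 3 h in all 3 fetal pairs, with medians of 6 heat-shock genes of −0.47, −0.68 and −0.69. A change in the mix of classes is argued against, because at least 97.6% of these medians was kept with class shares set equal. A change in cell temperature between LPS and PBS libraries, in the animal or at the bench, may be a cause and stays open: the Rbm3 ratios were 0.52, 0.39 and 0.40 and the Cirbp ratios 1.45, 1.06 and 1.36 in the fetal pairs, against 0.015 and −0.49 in the adult pair, where the heat-shock median was 0.32. Since each pair had 1 library per arm, handling and LPS cannot be told apart there. A direct LPS effect on these genes is the biological explanation and is equally open.

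Interferon genes were lower in fetuses of Il10-/- mothers at PBS, with a type I median of −0.67. A change in the mix of classes is argued against by −0.91 within HSC and multipotent progenitor-like cells. A high library of wild-type mothers as the whole cause is argued against by −0.56 relative to the wild-type fetal PBS library. The version of Cell Ranger stays open: the PBS median lay below the LPS median by −0.24, more than a counting difference acting alike on both would give, but the part shared by both ratios cannot be told apart from it. The mother's genotype is the biological explanation that the design names, and it was not tested.

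The edgeR test called 3032 genes between LPS at 3 h and PBS over the 3 fetal litter types. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest other count was 0. So few splits cannot give a share under 0.05. In the other splits, any difference between LPS and PBS libraries enters the residual, which in itself lowers their counts. The count of 0 is therefore no separate support.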

How the results depend on the processing

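The short-intron values, the runs without the low-UMI cluster and the mitochondrial limit for cells kept were chosen only after the result was seen. With 1 library per group, most values carry no test, and a list median counts as moved when it leaves the bootstrap interval over its members. Of 852 alternative results, those for main values left 123 unmoved, 39 moved, 9 reversed and 10 weaker, and those for single named genes in the test kept 573 past the threshold and lost 98, 54 of them without the litter block. Pairing was by litter type, and without that block the test called 43 genes, not 3032. With 1 litter type left out it called 1025 to 2706, with fewer libraries. The other 7 alternatives gave 2439 to 3648 genes. Camera called 13 lists with the preset correlation and 0 with the estimated one, and within classes, with fewer cells, 6 in cluster 7, 6 in early erythroid, 8 in HSC-like, 8 in late erythroid, 6 in megakaryocyte and 7 in monocyte progenitor-like cells. Apart from these counts, the cause was not tested.

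A pseudocount of 1 CPM, which damps low genes less by construction, gave type I interferon medians of 4.31 in the adult 3 h ratio, 2.40 in the adult 16 h ratio, 4.05 for adult less fetal at 3 h, 0.54 in the LPS ratio of Il10-/- mothers, 0.39 for the difference between mothers' LPS ratios and −1.01 between the mothers at PBS. It gave 1.93 for adult NF-kB genes at 3 h, and −0.30 and 0.52 for the genes chosen as higher and lower in wild-type fetuses. In HSC-like cells alone, values were 1.91 for adult NF-kB genes at 3 h, 0.51 for fetal secondary granule genes at 16 h, 0.74 for primary granule genes of adult over fetal cells, −0.034 for type I interferon in the LPS ratio of wild-type mothers (reversed), 0.37 and 0.36 for the mothers' difference in type I interferon and glucocorticoid responses, −0.91 for type I interferon between mothers at PBS and −0.077 for the chosen lower genes (reversed). In neutrophil progenitor-like cells alone, they were −0.46 for adult primary granule genes at 3 h, 1.53 and −0.48 for adult and fetal type I interferon at 16 h, 0.34 for fetal secondary granule genes at 16 h, 0.16 for primary granule genes of adult over fetal cells, −0.081 and −0.0068 for type I interferon with wild-type and Il10-/- mothers (both reversed), 0.15 for their difference and −0.27 for the chosen lower genes (reversed).

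TMM scaling gave type I interferon medians of 1.56 and −0.42 for adult and fetal cells at 16 h, and −0.35 for the chosen lower genes (reversed). With class shares set equal, adult primary granule genes at 3 h were at −0.43, fetal secondary granule genes at 16 h at 0.70, primary granule genes of adult over fetal cells at 0.36 and the chosen higher genes at 0.36 (reversed). With all members of at least 1 UMI, the fetal secondary granule median at 16 h was 0.60 and the interferon-gamma median of adult over fetal cells 0.47. Short-intron members gave 2.20 and −0.044 for type I interferon at 16 h in adult and fetal cells.

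Differences in class shares from PBS, in percentage points, moved with clustering. At resolution 1.2 they were −9.31 for adult neutrophil progenitor-like cells at 3 h, and 6.096 for neutrophil and −0.93 for HSC-like cells in the fetal 16 h library. At resolution 0.4 the fetal neutrophil value was 5.69. No maturing neutrophil-like class was named at either, so it has no value there. Without correction between libraries they were −58.0 for adult neutrophil progenitor-like cells at 3 h, and −9.16 (reversed), 37.4 and 0 (reversed) for neutrophil progenitor-like, maturing neutrophil-like and HSC-like cells of the fetal 16 h library. With at most 5% mitochondrial UMIs, which kept 2056 of its 3734 cells, those 3 values were 6.71, 5.003 and −1.01. The uncorrected values of −58.0, −9.16 and 37.4 points exceed the main shares, so these class names covered other cells there. The uncorrected 0 may mean that the HSC-like name held no cells of the compared libraries, so it cannot be read as an unchanged share.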

Other observations

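No test in this part was chosen after its result was seen, and the values given here were not tested.

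Adult cells held more transcripts of interferon and class II genes than fetal cells at 16 h of LPS as well, where both files came from 1 Cell Ranger version. Of the type I interferon genes measured, 28 of 31 were at least 2-fold higher in adult cells (median 2.15), as were 25 of 26 interferon-gamma genes (median 2.62) and 7 of 9 MHC class II genes (median 1.96). Secondary and tertiary granule genes went the other way, with 7 of 13 at least 2-fold lower in adult cells, 1 higher and a median of −1.24. The fetal progenitor programme stayed lower in adult cells, with 8 of 11 at least 2-fold lower and a median of −1.29. At 3 h, the same comparison gave medians of 3.54 for type I interferon genes, 2.78 for interferon-gamma genes and −1.38 for secondary granule genes.

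In HSC and multipotent progenitor-like cells, Socs3 stood at 12.2, 72.4 and 20.4 CPM in adult PBS, 3 h and 16 h libraries and at 3.27, 10.9 and 12.0 CPM in wild-type fetal ones. Isg15 in that class was at 29.95, 2248 and 217 CPM in adult and 77.5, 85.2 and 29.9 CPM in wild-type fetal libraries. The class joins clusters 0 and 1, and cluster 1 held 61.2%, 63.6% and 39.6% of it in the adult libraries and 44.1%, 44.3% and 50.2% in the fetal ones, so its levels at 16 h come from another mix. Basophil and mast cell progenitor-like cells made up 1.49%, 1.77% and 4.16% of the adult libraries, and cluster 7, which carries markers of 2 classes, 7.57%, 11.0% and 14.2%. The mast cell protease gene Cma1 was at 35.0 and 30.8 CPM and Tpsb2 at 36.0 and 26.3 CPM in the PBS and LPS libraries of wild-type mothers, and at 3.13 CPM or less in those of Il10-/- mothers. Cluster 14, with a median of 2077 UMIs, made up 11.5% of the library of Il10-/- mothers at LPS and 0.56% to 3.42% of the others. Cluster 13, with granule genes and called doublets, made up 4.86% of the PBS library of wild-type mothers. In the fetal 16 h ratio, Hist1h1b and Hist1h1e were at −3.58, the lowest of the named genes in that ratio, and in the mothers' comparison at LPS, Hist1h2ap was at 4.78 and the glycolysis gene Eno1 at 1.42.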
